A study of Mus musculus with 4 samples.

How the data were processed

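MacroH2A ChIP-seq was done in C2C12 cells at day 0 and day 5 of differentiation medium, per the labels. The series has 4 samples, of which 2 are macroH2A immunoprecipitations and 2 are input chromatin. The 2 immunoprecipitation libraries have island lists and were used, and the input samples were not analysed here. Both groups hold 1 library, so no test of differentiation was made.

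The deposited lists give chromosome, start, end and a whole-number count of ChIP reads per island, with no scaling that the values show. The submitters' processing notes name CASAVA 1.4, Bowtie2 2.2.6, SICER 1.1 and MACS 1.4.2, and the genome build mm9 (NCBIM37), without saying what each tool did. The names of the deposited lists give a SICER window of 600 bp, a gap of 1200 bp and a false discovery rate of 0.01. Whether the input libraries served as the control in island calling, and how duplicate reads were handled, is not stated in the labels. Starts and ends in the deposited lists fell on a 600 bp grid with inclusive ends, and islands of a list lay at least 1800 bp apart. Coordinates are printed counting from 1. Rows may be missing from a list, so a missing island means only that no row overlapped.

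Island number, covered length, width and reads per kb were computed for each library. An island was called shared when at least 1 bp overlapped an island of the other list, and shares have exact (Clopper-Pearson) 95% intervals. Chance overlap came from 1000 circular shifts of the myotube islands along each chromosome with a fixed seed of 7, and separately by chromosome. Chance shares of islands, in total and by width, came from 100 such shifts of the other list. Read density is reads per kb per 1000000 reads in islands, and the sum of island reads is not the library depth. Chromosome spans were taken up to the last island in either list, since chromosome lengths of mm9 were not at hand. Covered length was also summed in windows of 1 Mb. Where both lists had islands, the log2 ratio of their reads per kb was taken at each grid position, and its genome median was subtracted. Runs of at least 2 adjacent windows with at least 100 kb shared and a relative log2 ratio beyond 0.3 were listed.

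The regions named were set by rule before the data were examined. The rule takes per library the 5 widest islands, the 5 with most reads and the 5 library-specific islands with most reads, and per direction the 5 windows of 1 Mb with the largest difference in covered length. The density runs, the longest island-free stretches, the densest narrow islands and the last island of X were chosen after their values were seen.

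Gene-level results are not given. The gene annotation at hand was for GRCm38, another build, and on 6 of the 20 chromosomes islands ran past its last gene, by up to 7.20 Mb on chromosome 7. Alternatives tried left out the 25% of islands with fewest reads, merged islands within 5 kb, kept islands of at least 3 kb, required 50% overlap, 50% reciprocal overlap, autosomes only, equal covered length, shares of island reads in place of length, and scaling to reads in shared islands. Alternatives added after the data were seen included a floor of 70 reads per kb, unscaled or multiplied at day 5 by the genome median fold or by the ratio of median island densities. The overlap code was checked on simulated data, in which 59.4% of 30016 islands were kept in place. The others were moved to where they touched no myoblast island, so by construction 59.4% had to be found shared, and were. A map shifted at random gave an overlap of 1.00 times the mean of further shifts. The check covers the code and does not measure overlap by chance. A recomputed percentage counted as moved outside its exact interval, and an island number beyond 1.5 times. Ratios and the Jaccard index counted as moved beyond a 95% tolerance from island numbers alone, which is 1.62% for all islands, 7.13% for chromosome 15 and 9.73% for X. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.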

Results

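Chromatin immunoprecipitation followed by sequencing (ChIP-seq) mapped macroH2A, a histone H2A variant that carries a large globular macrodomain, in C2C12 cells. C2C12 is a mouse line of muscle precursors that exit the cell cycle and fuse into multinucleated myotubes when serum is lowered. One library came from myoblasts at day 0 of differentiation medium and one from myotubes at day 5. Each library is represented by a list of islands, which are stretches of enriched windows joined across short gaps, with the number of ChIP reads in each island. The islands held 24365482 reads at day 0 and 29619426 reads at day 5, 1.22 times as many. These totals count reads inside islands and are not the sequencing depth. With 1 library per group there was no test of differentiation and no p-value, and differences between days are differences between these 2 libraries. Intervals are at 95% and cover counting error only.

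The first question was how much of the genome macroH2A islands covered before and after differentiation. In myoblasts, 30016 islands covered 318 Mb, and in myotubes, 29473 islands covered 339 Mb. These lengths were 12.1% and 12.9% of the span up to the last island of each chromosome, so covered length at day 5 was 1.06 times that at day 0. MacroH2A lay in broad domains in both libraries. The median island was 7.2 kb wide at day 0 and 7.8 kb wide at day 5, and islands over 50 kb numbered 492 at day 0 and 562 at day 5. These wide islands made up 11.4% of the covered length in myoblasts and 12.7% in myotubes. Islands over 100 kb numbered 61 and 77. The median island held 506 reads at day 0 and 596 reads at day 5, which gives a relative counting error of 4.45% and 4.10%. The lowest read density of any listed island was 49.5 reads per kb at day 0 and 55.0 reads per kb at day 5, a ratio of 1.11, which was also the ratio of the median island densities. A floor of 70 reads per kb was also set at day 0. It was raised at day 5 by 1.14, the median density ratio over stretches covered at both days. The ratio of covered length then turned to 0.963, and with the floor unscaled it was 1.41. Its direction therefore depended on the scaling, and a floor raised by 1.11 was not tried for covered length.

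The widest myoblast island lay on chromosome 3 from 52306201 to 52541400 (mm9). It spanned 235 kb and held 21836 reads, and myotube islands covered 97.2% of it. The next widest in myoblasts was on chromosome 10 from 36934201 to 37141200. The other 3 of the 5 widest were on chromosome 15, from 25345201 to 25549800, from 102553201 to 102750600 and from 78389401 to 78577200. Myotube islands covered at least 87.0% of each of these 5. The widest myotube island was on chromosome 15 from 54719401 to 54990600, spanning 271 kb with 33132 reads. Myoblast islands covered 73.2% of it. Next in width at day 5 were islands on chromosome 1 from 71861401 to 72099000, chromosome 13 from 98188801 to 98422800, chromosome 3 from 52285201 to 52515000 and chromosome 2 from 117395401 to 117617400. The widest chromosome 3 domain was therefore among the 5 widest at both days.

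The second question was how far the myoblast and myotube maps coincided. Of the myoblast islands, 21444 (71.4%, exact binomial interval 70.9 to 72.0%) overlapped a myotube island by at least 1 bp. Of the myotube islands, 20182 (68.5%, 67.9 to 69.0%) overlapped a myoblast island. With the other list shifted at random, 22.1% of myoblast islands and 21.8% of myotube islands overlapped it. By length, 212 Mb were covered at both days, 106 Mb at day 0 alone and 126 Mb at day 5 alone, a Jaccard index (shared over joint length) of 0.478. Shifting the myotube islands along each chromosome 1000 times gave a mean shared length of 51.0 Mb and a highest of 59.3 Mb, so the measured overlap was 4.17 times the mean by chance. Requiring each of a pair of islands to cover 50% of the other lowered the shared islands to 33.7% at day 0 and 34.3% at day 5.

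Wide domains were shared more often than narrow ones. Of the islands over 50 kb, 490 of 492 at day 0 (99.6%) and 558 of 562 at day 5 (99.3%) overlapped the other list. Of islands up to 5 kb, 58.7% at day 0 and 52.3% at day 5 did. In shifted maps the myoblast shares were 49.6% for islands over 50 kb and 17.0% for those up to 5 kb, because wide islands meet others by chance more often. Shared islands had a median width of 8.4 kb at day 0 and 9.0 kb at day 5, against 5.4 kb and 6.0 kb for library-specific islands. Specific islands held 15.8% of the island reads in myoblasts and 16.7% in myotubes.

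Listed islands spanned a narrow range of read density, within which shared islands were slightly denser than specific ones. At day 0 the 5th and 95th percentiles over all islands were 61.8 and 94.5 reads per kb. At day 0 the median was 3.05 reads per kb per 1000000 island reads in shared islands and 2.85 in specific ones, a ratio of 1.07. At day 5 the medians were 2.79 and 2.62, again a ratio of 1.07. The lists hold only stretches that passed the caller's threshold, so a missing island does not show that macroH2A was absent.

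Among islands seen at day 0 alone, the one with the most reads was on chromosome 10 from 119838001 to 119903400, 65.4 kb wide with 6398 reads. The next 4 were all on chromosome 15, from 32218201 to 32287200, from 61821001 to 61869600, from 7318201 to 7368000 and from 12416401 to 12456600. Among islands seen at day 5 alone, a 6.0 kb island on chromosome 2 from 98502001 to 98508000 held 17945 reads, or 2991 reads per kb. That is 37.0 times the median myotube island, and no myoblast island lay within 1 Mb. A 125 kb island on chromosome 17 from 30766201 to 30891600 followed with 12814 reads at 102 reads per kb. The other 3 were on chromosome 9 from 3015001 to 3038400 at 493 reads per kb, and on chromosome 15 from 71976001 to 72073200 and from 91756201 to 91809600. The chromosome 9 island had 6.09 times the median density, also with no myoblast island within 1 Mb. Input reads were not analysed, so the extreme densities on chromosomes 2 and 9 do not show a gain of macroH2A. Single islands can be missing from a list for reasons other than their read density, which a comparison of 1 list per day cannot separate.

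The third comparison asked where along the chromosomes macroH2A islands lay. Chromosome 15 stood apart, with 31.2% of its span covered in myoblasts and 33.8% in myotubes. The other 18 autosomes together were covered over 11.7% and 12.6%, so chromosome 15 was 2.66 times as covered at day 0 and 2.69 times at day 5. It held 11.5% of all island reads at day 0 and 12.4% at day 5, and 132 of 492 and 155 of 562 islands over 50 kb. Its islands averaged 20.0 kb at day 0 and 21.5 kb at day 5, 1.97 and 1.96 times those of the other autosomes, and were 1.35 and 1.37 times as many per Mb. In number chromosome 15 was not the highest, with 15.6 and 15.7 islands per Mb against up to 17.8 and 17.7 on another autosome. No other autosome had a mean island width above 12.3 kb at day 0 or 12.5 kb at day 5. Chromosome 10 came next in coverage with 21.8% and 22.1%, then chromosome 11 with 19.6% and 20.2%. Chromosome 7 was the least covered autosome, at 2.90% and 3.45%. The Jaccard index of the 2 maps was 0.652 on chromosome 15 and 0.291 on the X chromosome. The overlap was 2.43 times that of shifted maps on chromosome 15 and 9.79 times on X. Both measures depend on how much is covered, in opposite directions, so they do not rank the chromosomes.

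**Figure D1:**
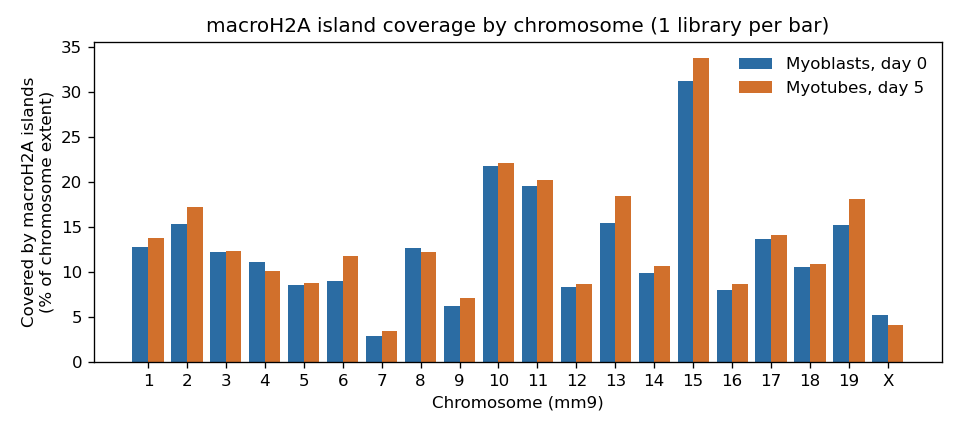
Percent of each mouse chromosome's span covered by macroH2A islands (vertical axis) by chromosome (horizontal axis), in myoblasts at day 0 and myotubes at day 5, 1 library per bar. Chromosome 15 is the most covered at both days (31.2% and 33.8%), and the X chromosome is at 5.23% at day 0 and 4.11% at day 5.

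The X chromosome was less covered in the myotube library than in the myoblast library, while 17 of the 19 autosomes were more covered. Covered length on X went from 8.71 Mb in 1085 islands at day 0 to 6.84 Mb in 756 islands at day 5, a ratio of 0.785. The autosomes together had a ratio of 1.07, which leaves X at 0.733 relative to them. Of the myoblast X islands, 57.0% met no myotube island, against 27.5% of autosomal islands. In reverse, 41.5% of myotube X islands met no myoblast island, against 31.3% on autosomes. Thinly covered chromosome 7 was also high in both directions, at 39.5% and 47.4%, so these shares do not by themselves show loss from X. Among autosomes the ratio of covered length ran from 0.912 on chromosome 4 to 1.31 on chromosome 6, and chromosome 8, at 0.965, was the other one below 1. Chromosomes 7, 13 and 19 had ratios of 1.19, 1.19 and 1.18. With the scaled floor X stood at 0.672 relative to the autosomes and the lowest autosome at 0.827; the same floor left unscaled kept 474 of 1085 X islands at day 0 and 593 of 756 at day 5, and by that construction X stood at 1.03. The myotube list was also reduced to the covered length of the myoblast list by keeping its densest islands, down to 69.2 reads per kb. Then 9 of the 19 autosomes were more covered at day 5, X stood at 0.630 relative to the autosomes and the lowest autosome at 0.844. Myotube islands on X were less dense (median 75.6 reads per kb, against 81.1 on autosomes). By that construction the cut takes more from X, so the lower ratio is not separate evidence.

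In windows of 1 Mb, chromosomes differed in the balance of higher and lower coverage. Of 2645 windows, 1240 had more covered length at day 5 and 888 had less. On chromosome 13, 80 windows had more and 27 less, and on chromosome 6, 81 had more and 31 less. On X, 37 had more and 70 less. Covered length per window at the 2 days had a Pearson correlation of 0.932 and a Spearman correlation of 0.939 across windows, which are not independent replicates. All windows were included, also the 507 with no island in either library. The median absolute difference was 17.4 kb per window, which those empty windows lower.

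**Figure D2:**
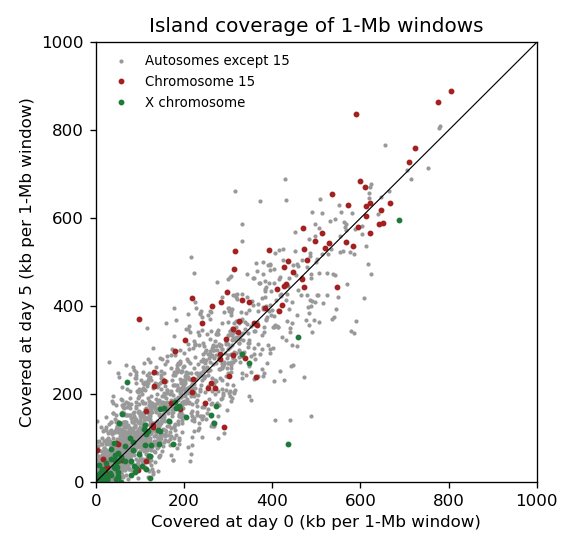
Length covered by macroH2A islands in each 1-Mb window at day 0 (horizontal axis, kb) against day 5 (vertical axis, kb), with chromosome 15, the X chromosome and other autosomes in separate colours and the line of equal coverage. Most windows follow the line (Pearson 0.932), chromosome 15 windows reach the upper end, and the X window at 96 Mb is far below it (436 kb at day 0 and 86.4 kb at day 5).

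The largest gains of covered length were in 3 windows of chromosome 13 and 1 each of chromosomes 15 and 10. Chromosome 13 from 109 to 110 Mb went from 316 kb to 662 kb, from 16 to 17 Mb from 215 kb to 512 kb, and from 5 to 6 Mb from 373 kb to 639 kb. Chromosome 15 from 91 to 92 Mb went from 98.4 kb to 371 kb, and chromosome 10 from 16 to 17 Mb from 429 kb to 690 kb. The largest losses were on X from 96 to 97 Mb, from 436 kb to 86.4 kb, and on chromosome 4 from 81 to 82 Mb, from 487 kb to 150 kb. Chromosome 18 from 54 to 55 Mb went from 440 kb to 142 kb, chromosome 10 from 83 to 84 Mb from 406 kb to 140 kb, and chromosome 5 from 112 to 113 Mb from 585 kb to 339 kb. Windows that gained more than 200 kb numbered 16, and windows that lost more than 200 kb numbered 8. With the scaled floor, the X window differed by -228.6 kb and chromosome 13 from 16 to 17 Mb by 153.8 kb, each over 1.5 times from the full lists.

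Among 1-Mb windows with at least 100 kb covered at both days, 2 runs of adjacent windows on chromosome 15 had higher read density at day 5. Across the genome, the median log2 ratio of reads per kb, day 5 over day 0, was 0.19, and the log2 ratios and folds below are relative to it. From 54 to 57 Mb on chromosome 15 the relative log2 ratio was 0.46 (1.38-fold), with mean density in islands of 3.70 at day 0 and 5.06 at day 5, in reads per kb per 1000000 island reads, and coverage going from 70.6% to 82.9%. From 62 to 64 Mb it was 0.78 (1.72-fold), with densities of 3.998 and 6.09 and coverage going from 65.3% to 70.4%. One more run of adjacent windows passed a relative log2 ratio of 0.3, on chromosome 2 from 116 to 118 Mb, at 0.33 (1.25-fold). No run of adjacent windows was lower at day 5 by as much. The rule for these runs was set after the data were seen.

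All 5 myotube islands with the most reads lay in these 3 runs, 4 of them on chromosome 15. Their densities are given unscaled. The island with the most reads, on chromosome 15 from 56428201 to 56634600, held 39720 reads at 192 reads per kb (190.6 to 194.3), and the myoblast islands beneath it averaged 88.6 reads per kb. The island from 62201401 to 62347200 held 32479 reads at 223 reads per kb (220.3 to 225.2), against 109 reads per kb at day 0. The island from 55234801 to 55425000 had 156 reads per kb, against 99.7 at day 0. In myoblasts the most read-rich islands were on chromosome 3 from 52306201 to 52541400 and from 121227001 to 121397400, and on chromosome 15 from 78389401 to 78577200, from 102553201 to 102750600 and from 101125801 to 101304000. Input reads were not analysed here, so a density ratio does not separate macroH2A from the amount of DNA.

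**Figure D3:**
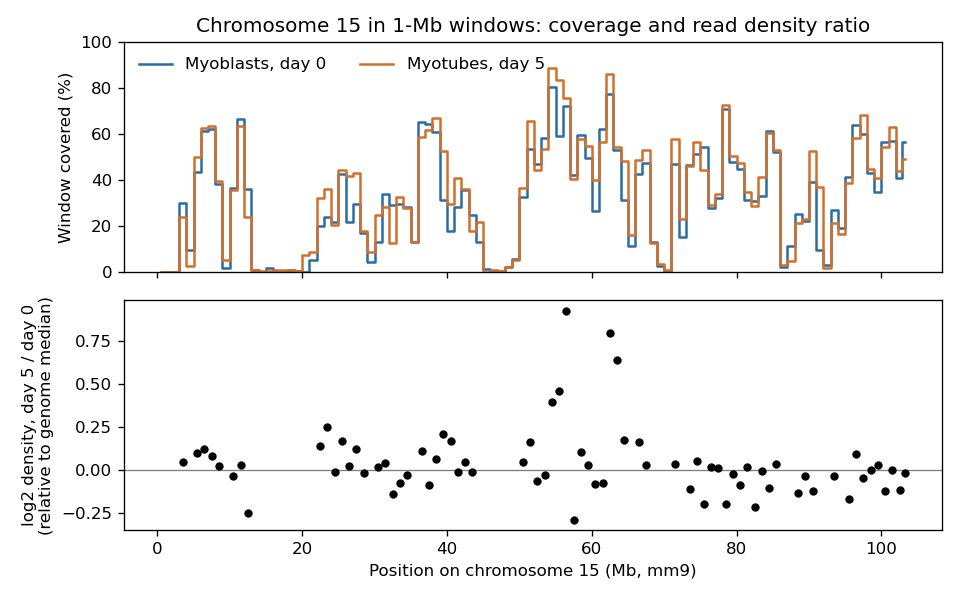
Chromosome 15 in 1-Mb windows by position (Mb, mm9), with the percent of each window covered by macroH2A islands at day 0 and day 5 in the upper panel and the log2 read density ratio, day 5 over day 0 relative to the genome median, in the lower panel. Windows from 54 to 57 Mb and from 62 to 64 Mb stand above the rest in density ratio, with run medians of 0.46 and 0.78.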

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

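Shifts over 200 to 2000 kb, leaving out chromosome 15, leaving out islands over 400 reads per kb, floors of 70 reads per kb, and every setting for the named windows were chosen after seeing the data. Of the 76 recomputed values for the main comparisons 2 reversed, and 34 stayed within the tolerance set for each. That tolerance was 1.62% for ratios over all islands, 7.13% for chromosome 15 and 9.73% for X, so the same shift can be outside for one and inside for another. Without the 25% of islands with fewest reads, the shared percentages were 70.3 (day 0) and 67.3 (day 5), the Jaccard index 0.464 and the overlap over chance 4.33. Merging islands within 5 kb gave by construction fewer islands, 18463 and 18468, with 69.4% and 67.2% shared, a Jaccard index of 0.514 and an overlap 4.07 times chance. Stricter overlap lowered sharing by construction, to 62.5% and 57.5% with 50% of the island covered, and to 33.7% and 34.3% with reciprocal overlap. On autosomes alone 72.5% of day 0 islands were shared. At equal covered length, with the least dense myotube islands cut, the overlap was 4.25 times chance. The X ratio relative to autosomes was 0.630, which that cut lowers by construction. By share of island reads, chromosome 15 was 3.06 and 3.32 times the other autosomes. Scaled to reads in shared islands, their median density was 3.62 and 3.35 reads per kb per 1000000 reads. Shifts of 200 to 2000 kb, which keep regional clustering, lowered the overlap to 2.98 times chance by construction. Without chromosome 15 the Jaccard index was 0.460 and the overlap 4.65 times chance. With an unscaled floor of 70 reads per kb, which by construction cuts the less dense day 0 list more, 19234 islands were left at day 0 and 26636 at day 5. Covered length at day 5 was 1.41 times that at day 0, 75.6% and 52.8% were shared, the Jaccard index was 0.445 and the overlap 4.62 times chance. Chromosome 15 stood at 3.68 and 2.91 times the other autosomes, and the X ratio reversed to 1.03, with 474 X islands left of 1085 at day 0 and 593 of 756 at day 5. With the floor scaled at day 5, 19234 and 16041 islands were left, the covered length ratio reversed to 0.963, 57.2% and 61.7% were shared, the Jaccard index was 0.448, the overlap 5.14 times chance and chromosome 15 at 3.68 and 4.01, while the X ratio was 0.672. For other changes the cause was not tested. Leaving out islands over 400 reads per kb removed only 5 myotube islands and no myoblast island. Its 10 values could therefore hardly move, and all 10 are among the 34 within tolerance. The 10 named windows kept their direction in all 50 recomputed values, 5 of which differed by more than 1.5 times. They were picked for the largest differences in these same lists, so a kept direction was likely beforehand and is not separate support. Gene coverage and gene list coverage, and their alternatives, were not run for lack of an annotation of the build. With 1 library per group, variation between cultures was not measured.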

Other observations

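All tests of explanations in this part were chosen after the results were seen. The macroH2A maps left long stretches without an island at either day. The longest was on X from 109886401 to 123322200 (13.4 Mb), followed by chromosome 7 from 39022201 to 50591400 (11.6 Mb) and chromosome 6 from 73327201 to 81034800 (7.71 Mb). Of the 2645 windows of 1 Mb, 507 had no island in either library, and 60 of these were on X and 56 on chromosome 7. Whether reads could be placed in these windows was not examined, so an empty window does not show that macroH2A was absent. At the other end, 62 windows were covered over more than 500 kb at both days, 23 of them on chromosome 15. The 264 most covered windows held 38.7% of the covered length in myoblasts and 37.3% in myotubes.

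The last island of X, from 166407601 to 166447200, had the same borders at both days and 203 reads per kb at day 0 and 229 at day 5, or 8.33 and 7.74 per 1000000 island reads. Islands over 400 reads per kb numbered 0 at day 0 and 5 at day 5, and together held 0.128% of the myotube island reads. They lay on chromosome 2 at 98.5 Mb, chromosome 9 at 35.1 Mb with 1103 reads per kb, chromosome 12 at 3.11 Mb and chromosome 9 at 2999401 and 3015001. Myotube islands spanned several myoblast islands more often than the reverse: 4131 (14.0%) spanned at least 2, against 3363 (11.2%) of myoblast islands. Myotube islands were also wider, with a median of 7.8 kb against 7.2 kb, and these counts were not compared with shifted maps. Overlap with the other list rose with width, from 66.3% of day 0 islands of 5 to 10 kb to 84.5% at 10 to 20 kb and 96.9% at 20 to 50 kb, against 19.9%, 25.6% and 34.7% in shifted maps.

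On chromosome 15, read density was higher at day 5 from 54 to 57 Mb and from 62 to 64 Mb. The runs were picked for a high ratio, so library depth was not tested on them. One gained DNA segment that holds both runs is argued against by the stretch from 57 to 62 Mb, where the median was -0.052. The SD of the ratio inside the first run was 0.38, while 187 overlapping stretches of 2 Mb elsewhere had a 95th percentile of 0.23 and a highest of 0.27. The first run is 3 windows of 1 Mb, at 0.39, 0.46 and 0.93, so it is longer than those stretches. A gain with borders inside the run would also raise the SD, so one gained segment there is not decided. For the second run the SD was 0.21, below that percentile. A single gained segment may explain either run, as may more macroH2A in myotubes or shorter gains within a run. Input reads would have to separate these.

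Chromosome 15 was more covered than the other autosomes at both days. A candidate explanation is extra copies of all of chromosome 15 in C2C12. Among islands of 4.8 to 12 kb, read density was above the 95th percentile of 10-Mb segments of other autosomes in 10 of 11 chromosome 15 segments at each day, but the lowest, 1.02 times the other autosomes, was below that percentile of 1.04 at day 0 and 1.037 at day 5. Segments ran up to 1.17 times at day 0 and 1.18 times at day 5, with an SD of log2 ratios of 0.065 and 0.064, and the highest of any other autosome was 0.053 and 0.045. One copy number for the whole chromosome is therefore left open, as are copy gains of parts and a preference of macroH2A for this chromosome, which was not tested.

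The X chromosome was less covered at day 5. A difference in the density at which islands were listed was not settled. A floor was set at 70 reads per kb at day 0 and its equivalent at day 5. The X ratio relative to autosomes was then 0.729 scaled by the median island and 0.672 scaled by the genome median. The lowest autosomes were at 0.840 and 0.827. However, the median day 0 island on X, at 68.9 reads per kb, lay below that floor, and the median autosomal island, at 73.1, lay above it. X therefore depends more on the floor and its scaling, and stood at 1.03 with the floor unscaled. A few windows as the whole cause are argued against, since without the 5 X windows that lost most the ratio was 0.798, below the lowest autosome at 0.851. In stretches covered at both days the relative log2 density of X was -0.059, below the autosomal range of -0.03 to 0.03. Fewer X copies in the myotube culture or less macroH2A on X at day 5 may each give this lower density. So may the listing density left unsettled above, since X islands were less dense. In islands of 4.8 to 12 kb, X density was 0.962 (day 0) and 0.955 (day 5) times that of autosomes other than 15, a small change. Input reads would have to separate copies from macroH2A.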
